A study of Mus musculus with 10 samples.

How the data were processed

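RNA was measured in 10 libraries from mouse inguinal cultures labelled primary white adipocytes from male C57BL/6 mice, 5 groups of 2: saline, BAFF and APRIL (recombinant, 500 ng/ml each), LPS (100 ng/ml) and norepinephrine (1 mM), each for 24 h. Per the labels, cells from digested fat were grown to confluence and total RNA was made into TruSeq libraries. The authors quantified transcripts with kallisto (version not given) and name the mm10 genome, and per the file headers each file holds TPM (tpm) for 28987 Ensembl gene IDs. The annotation release, the way transcripts were summed to genes and any filter are not stated. Each library sums to between 953553 and 964726 TPM, so part of each library's transcripts is not listed. The files hold no counts, so read depth and counting precision per library are not analysed here, and replicate spread is the only measure of error. Mitochondrially encoded genes took 14.4 to 21.6% of each library's transcripts, and the gene mt-Atp8 alone 7.12 to 13.2%.

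The comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. That plan put a count-based test first and set the test used here as the fallback for TPM. Genes with at least 1 TPM in at least 2 libraries (14166) were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend, all 10 libraries in 1 fit of 5 group means without a block, 5 residual degrees of freedom, and Benjamini-Hochberg adjustment at 0.05 within each comparison. Every adjusted p of a gene is from this limma fit. A group of 2 is thereby assumed to vary like the other groups. The 2 libraries labelled APRIL enter this spread, and they correlated at 0.971 across genes, the lowest within a group, where the highest was 0.988. The comparisons are each treatment against saline and BAFF against the libraries labelled APRIL. Symbols and positions came from GENCODE mouse M21, which matched 27458 of the 28987 IDs and left 281 tested IDs without a symbol, and 17 tested IDs hold values identical to those of another ID.

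The lists number 34, with 23 pathways and 11 cell types, and hold 585 genes, of which 575 are in the files. The 29 lists with at least 5 tested members were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the lists within each comparison, and again with the correlation estimated from the data. Camera sets the mean test statistic of a list against that of all other genes, so its direction can differ from the sign of the list's median. The cytosolic heat-shock, circadian clock and peroxisome lists were added after the values were seen. Members past 0.05 were counted over all genes and adjusted over the list alone.

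Genes were named by rule. For each comparison with saline these are the 10 largest rises and the 10 largest falls past 0.05 with a mean of at least 5 TPM over the 10 libraries and both treated libraries beyond both saline libraries, and for BAFF against the libraries labelled APRIL 5 and 5. Where fewer passed, the genes of smallest p made up 5, and unnamed gene models and pseudogenes were skipped. Up to 4 members of each list with the smallest p, the BAFF and APRIL ligand and receptor genes, Adrb1, Adrb3 and Tlr4 were added. Some genes that this rule names are not reported here. The Y-linked genes, Tsix, Gm7336 and ENSMUSG00000080830 were named after their values were seen.

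Sensitivity was checked on simulated data, in which fold changes of 1.5, 2 and 4 were added to 200 genes in each of 20 draws for BAFF against saline. Of all gene calls 5.96% were false. The 1 list scored, of interferon-stimulated genes, was called in 20 of 20 draws when raised as a whole and in 0 when unchanged. The draws took genes as independent, so they cannot show false list calls that arise from correlation between genes. Covariances between comparisons that share saline were set beside 100 simulated draws of unchanged groups and recomputed with 1 saline library for each side. Alternatives were other filters, pseudocounts of 0.1 and 0.5, the 4 compared libraries alone, a block on the replicate number, a 1.5-fold minimum, each library left out, fry of limma and the estimated correlation. Added after the data were seen were median-ratio scaling, mitochondrially encoded genes left out, identical values counted once, and the libraries labelled APRIL left out. Copies of the named genes were searched with BLAST 2.17.0 in the transcripts of the same GENCODE release, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The transcript Xist is not analysed here.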

Results

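RNA sequencing measured transcript levels in 10 libraries from mouse cell cultures whose source is given as primary white adipocytes, grown from digested inguinal fat of male C57BL/6 mice. The cultures fall into 5 groups of 2 libraries, each treated for 24 h: saline, the recombinant TNF-family ligands BAFF and APRIL at 500 ng/ml each, bacterial lipopolysaccharide (LPS) at 100 ng/ml, and norepinephrine at 1 mM. The treatment text speaks of adipose tissue where the source label speaks of adipocytes. The series title concerns a BAFF and APRIL axis in weight gain on an obesogenic diet. Each library lists 28987 genes in TPM, the relative abundance of each gene's transcripts within the library, summing to between 953553 and 964726 TPM, with 12845 to 13115 genes at 1 TPM or more. The sequencing depth behind these values is unknown, because the files hold no counts. The labels do not say whether the 2 libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these samples. Group levels are means ± SD with n = 2 libraries, and fold changes (± SE) are differences of log2(TPM + 1), which understate changes of genes with low TPM. Tests covered 14166 genes at 1 TPM or more in at least 2 libraries. Over these genes the log2 fold changes against saline had a median of 0.11 with BAFF, 0.08 in the libraries labelled APRIL, -0.01 with LPS and 0.04 with norepinephrine, and scaling the libraries by median ratios moved the first to 0.000416 and the second to -0.03. For a list of genes, the relative median is the median log2 fold change of its tested members minus that of all tested genes.

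The 2 libraries labelled APRIL stood apart from the other 8. The first principal component, with 60.7% of the variance, separated them from the rest, while the next component, with 13.9%, set the LPS libraries off. Their correlations with the other libraries, across genes on the log2 scale, ran from 0.850 to 0.886, against 0.948 to 0.991 among the other 8. The labels give all mice as male, but the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 0.489 and 0.775 TPM in the libraries labelled APRIL and to between 93.8 and 123 TPM in the others. Tsix, the antisense partner of the X-inactivation transcript, stood at 7.39 ± 0.445 TPM in the libraries labelled APRIL and at 0.00406 ± 0.00575 TPM with saline.

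**Figure D1:**
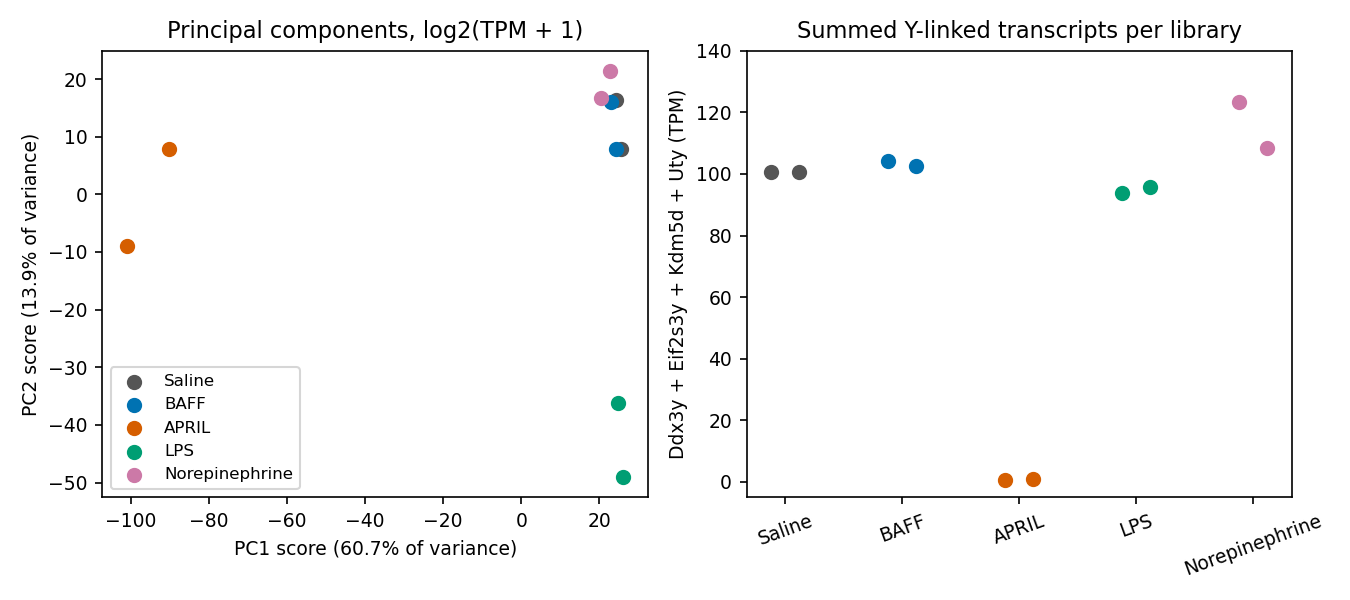
Left: the first 2 principal components of log2(TPM + 1) over the tested genes, 1 point per library, axes in component scores with the percent of variance. Right: summed TPM of 4 Y-linked genes per library, 0.489 and 0.775 in the libraries labelled APRIL and 93.8 to 123 in the other 8.

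The genes of the ligands and receptors themselves stood at 5.44 TPM or less in each of the 10 libraries. Of the list of BAFF and APRIL ligands and receptors, 2 genes had enough signal to be tested, Tnfsf13b (BAFF) and Tnfsf13 (APRIL), and none passed in any of the 5 comparisons by limma. Tnfsf13b stood at 2.97 ± 0.334 TPM with saline, 3.296 ± 0.821 with BAFF, 4.77 ± 0.946 with LPS, 2.59 ± 0.603 with norepinephrine and 2.16 ± 0.685 in the libraries labelled APRIL, and Tnfsf13 at 0.868 ± 0.543 TPM with saline. The receptor genes Tnfrsf13b (TACI), Tnfrsf13c (BAFF receptor) and Tnfrsf17 (BCMA) were below the level for testing, at 0.275 ± 0.0902, 0.0976 ± 0.00990 and 0.0270 ± 0.0382 TPM with saline. Among B-lymphocyte markers Ighm was the only gene tested, at 1.97 ± 0.170 TPM with saline and 1.93 ± 0.749 with BAFF. Of the receptors of the control treatments, Tlr4, the LPS receptor, stood at 11.1 ± 0.827 TPM, and the adrenergic receptors Adrb1 and Adrb3 at 0.300 ± 0.0282 and 130.0 ± 15.1 TPM with saline.

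LPS against saline shows how these cultures responded to a bacterial inflammatory stimulus. Cultures treated with LPS carried far more transcript for chemokines, acute-phase proteins and antigen presentation. They carried less for several adipocyte and stress-response genes. Saa3 (mm10 ENSMUSG00000040026, chromosome 7, 46711998 to 46715700) encodes an acute-phase protein of adipocytes and macrophages. It showed the largest rise among the named genes, from 106 ± 84.7 to 16930.3 ± 4016 TPM (log2 fold change 7.57 ± 0.72, adjusted p = 0.00209). Cxcl5, a neutrophil-attracting chemokine, rose from 5.46 ± 2.06 to 685 ± 127 TPM (log2 fold change 6.76 ± 0.32, adjusted p = 0.000305). Car3, a carbonic anhydrase abundant in adipocytes, showed the largest fall among them, from 883 ± 31.8 to 51.6 ± 24.3 TPM (log2 fold change -4.15 ± 0.55, adjusted p = 0.00714). By limma, 407 genes rose and 132 fell at a false discovery rate of 0.05, and 261 and 75 of these changed at least 2-fold.

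The inflammatory lists moved most with LPS. Of 21 tested cytokines and chemokines 15 rose and 0 fell (18 and 0 adjusted over the list alone). Their relative median was 3.28 (camera adjusted p = 2.39e-26, 0.0220 with an estimated correlation). Il1b, the precursor of a fever-inducing cytokine, rose from 0.185 ± 0.262 to 88.4 ± 60.3 TPM (adjusted p = 0.000644). The T-cell attractant Ccl5 rose from 1.87 ± 1.23 to 220.4 ± 151 TPM (adjusted p = 0.00106) and the neutrophil attractant Cxcl1 from 2.91 ± 0.494 to 213 ± 5.54 TPM (adjusted p = 0.000414). Il1a (log2 fold change 3.85, adjusted p = 0.000331) and Cxcl3 (log2 fold change 6.36, adjusted p = 0.000414) rose with them. Of 19 acute-phase and innate response genes 14 rose and 0 fell (15 and 0 adjusted over the list alone). The list's relative median was 2.87 (camera adjusted p = 3.03e-20, 0.0220 with an estimated correlation). Lcn2, which binds bacterial siderophores, rose from 23.2 ± 0.869 to 1211 ± 46.0 TPM (adjusted p = 0.00165). The complement genes Cfb and C3 rose, Cfb from 41.1 ± 7.71 to 1146 ± 144 TPM (adjusted p = 0.000414) and C3 from 83.7 ± 19.1 to 534 ± 40.5 TPM (adjusted p = 0.000683). Nos2, the inducible nitric oxide synthase, rose from 1.68 ± 0.884 to 70.9 ± 33.1 TPM (adjusted p = 0.000846). These are the 2 lists whose call held with an estimated correlation. Of 21 NF-kB pathway and feedback genes 11 rose and 0 fell (18 and 0 adjusted over the list alone). As a list they had a relative median of 1.13 (camera adjusted p = 2.88e-17, 0.197 with an estimated correlation). Among them were Nfkbiz (log2 fold change 1.67, adjusted p = 0.000507), the mitochondrial superoxide dismutase Sod2 (log2 fold change 2.14, adjusted p = 0.000941) and the NF-kB subunit Relb (log2 fold change 1.27, adjusted p = 0.00250). Of 11 genes of antigen processing and MHC class I 10 rose and 0 fell (11 and 0 adjusted over the list alone). Across the list the relative median was 1.48 (camera adjusted p = 4.62e-16, 0.112 with an estimated correlation). The class I heavy chain H2-K1 rose from 406 ± 35.6 to 1428 ± 229 TPM (adjusted p = 0.00142) and the peptide-loading factor Tapbp from 204 ± 18.4 to 620.3 ± 87.6 TPM (adjusted p = 0.00220). Of 27 interferon-stimulated genes 5 rose and 0 fell (19 and 0 adjusted over the list alone). Relative to all genes their median stood at 1.34 (camera adjusted p = 1.84e-15, 0.351 with an estimated correlation). The guanylate-binding protein Gbp2 rose from 15.6 ± 2.37 to 102 ± 3.59 TPM (adjusted p = 0.00424). Arginase Arg1 (log2 fold change 5.46, adjusted p = 0.0146), the matrix protease Mmp3 (log2 fold change 5.37, adjusted p = 0.00700) and the protease inhibitor Serpinb2 (log2 fold change 4.96, adjusted p = 0.000454) completed the 10 largest rises. In lists too small to test, 1 of 3 neutrophil and mast cell genes rose, S100a8, from 0.789 ± 0.593 to 16.7 ± 3.99 TPM (adjusted p = 0.00340). So did 1 of 2 blood genes, the platelet chemokine Ppbp, from 0.0202 ± 0.0286 to 7.47 ± 5.48 TPM (adjusted p = 0.00836). The macrophage list was not called (camera adjusted p = 0.401). Of its 19 tested genes 0 rose and 0 fell by limma, with 3 higher and 0 lower at an unadjusted p under 0.05.

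The lists of stress-response, adipocyte identity, lipolysis and smooth muscle genes were called lower with LPS. Of 20 genes of the unfolded protein and integrated stress response 1 rose and 4 fell (1 and 8 adjusted over the list alone). Together they had a relative median of -0.43 (camera adjusted p = 6.43e-06, 0.259 with an estimated correlation). Ddit3 (CHOP), a transcription factor of stress-induced cell death, fell from 123 ± 15.6 to 40.9 ± 3.36 TPM (adjusted p = 0.000858), and the pseudokinase Trib3 from 38.5 ± 3.14 to 8.38 ± 1.69 TPM (adjusted p = 0.00144). The mTORC1 inhibitor Ddit4 rose from 68.7 ± 6.04 to 141 ± 11.3 TPM (adjusted p = 0.0327). Derl3, a factor of protein degradation at the endoplasmic reticulum outside that list, fell from 27.9 ± 7.30 to 5.91 ± 0.143 TPM (adjusted p = 0.00131). Of 18 adipocyte identity genes 1 rose and 0 fell (1 and 4 adjusted over the list alone). Such genes had a relative median of -0.57 (camera adjusted p = 0.00468, 0.705 with an estimated correlation). The gene that rose was Cebpb, an early differentiation factor, from 85.3 ± 9.57 to 208 ± 16.2 TPM (adjusted p = 0.0417). The insulin-responsive glucose transporter Slc2a4 did not pass, at 15.7 ± 1.62 TPM with saline and 4.36 ± 0.969 with LPS (adjusted p = 0.0638). Of 20 lipolysis and lipid droplet genes 0 rose and 3 fell (the same adjusted over the list alone). Set against all genes, they had a relative median of -0.39 (camera adjusted p = 0.0417, 0.714 with an estimated correlation). The lipase inhibitor G0s2 fell from 299 ± 23.9 to 121 ± 1.63 TPM (adjusted p = 0.00525) and the glycerol channel Aqp7 from 21.2 ± 2.10 to 6.22 ± 2.67 TPM (adjusted p = 0.0343). The receptor Adrb3 fell from 130.0 ± 15.1 to 50.8 ± 1.19 TPM (adjusted p = 0.0497). Of 20 fatty acid and triglyceride synthesis genes 0 rose and 1 fell (1 and 3 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0707). The gene that fell was the lipogenic factor Thrsp (log2 fold change -2.66, adjusted p = 0.00601). Of 11 smooth muscle and pericyte genes 0 rose and 2 fell (0 and 5 adjusted over the list alone). This list had a relative median of -0.48 (camera adjusted p = 0.000215, 0.259 with an estimated correlation). The muscle myosin Myh11 (log2 fold change -1.42, adjusted p = 0.0484) and the proteoglycan Cspg4 (log2 fold change -1.05, adjusted p = 0.0489) fell. Of 15 preadipocyte and fibroblast markers 4 rose and 1 fell (6 and 2 adjusted over the list alone). That list was not called (camera adjusted p = 0.291), and its median of -0.10 and mean of 0.39 had opposite signs. The matrix proteoglycan gene Dcn rose from 150.3 ± 32.1 to 933 ± 355 TPM (adjusted p = 0.00712) and the progenitor marker Pi16 from 0.566 ± 0.131 to 2.82 ± 0.318 TPM (adjusted p = 0.00794). Pdgfra rose from 68.2 ± 2.99 to 129.5 ± 7.30 TPM (adjusted p = 0.0380), while the actin-binding Gsn fell from 1253 ± 49.7 to 669.9 ± 38.8 TPM (adjusted p = 0.0211). Outside the lists, the secreted matrix proteins Sfrp2 (log2 fold change -2.11, adjusted p = 0.00340) and Cilp (log2 fold change -2.003, adjusted p = 0.00142) were among the 10 largest falls, with Lrrc17, Tmem45b, Aspn and Serpina3c.

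Other list shifts with LPS went both ways. The hypoxia list was called higher, and of 19 genes 3 rose and 0 fell (5 and 0 adjusted over the list alone). Their relative median was 0.35 (camera adjusted p = 7.29e-06, 0.296 with an estimated correlation). Hk2, P4ha2 and Ldha rose, Ldha from 855 ± 42.7 to 1195 ± 21.1 TPM (adjusted p = 0.0422). The NRF2 and metallothionein list was called higher, and of 16 genes 2 rose and 0 fell (the same adjusted over the list alone). The list's relative median was 0.58 (camera adjusted p = 0.000245, 0.567 with an estimated correlation). The metal-binding Mt1 (log2 fold change 1.59, adjusted p = 0.00510) and Mt2 (log2 fold change 1.82, adjusted p = 0.00377) rose. The cAMP/CREB list was called higher, and of 22 genes 3 rose and 1 fell (9 and 1 adjusted over the list alone). As a list they had a relative median of 0.37 (camera adjusted p = 0.00182, 0.522 with an estimated correlation). The cAMP phosphodiesterase Pde4b (log2 fold change 1.30, adjusted p = 0.00266), Id2 (log2 fold change 0.76, adjusted p = 0.0101) and the kinase Sik1 (log2 fold change 0.94, adjusted p = 0.0188) rose, and Rgs2 (log2 fold change -1.27, adjusted p = 0.0420) fell. Of 20 insulin and glucose genes 2 rose and 0 fell (6 and 3 adjusted over the list alone), Hk2 and Ldha, and the list was called higher (camera adjusted p = 0.0417, 0.714 with an estimated correlation). Called lower without a member past the threshold by limma, over all genes or adjusted over the list alone, were 3 lists. Mitochondrially encoded genes had 0 higher and 1 lower at an unadjusted p under 0.05. Across the list the relative median was -0.26 (camera adjusted p = 0.00158, 0.567 with an estimated correlation). The nuclear-encoded respiratory chain had 0 higher and 0 lower at an unadjusted p under 0.05. Relative to all genes their median stood at -0.15 (camera adjusted p = 0.0330, 0.714 with an estimated correlation). Cytosolic ribosomal proteins had 0 higher and 0 lower at an unadjusted p under 0.05. Together they had a relative median of -0.05 (camera adjusted p = 0.0417, 0.714 with an estimated correlation). The p53 list was not called (camera adjusted p = 0.520), though Fas rose from 10.2 ± 0.995 to 34.6 ± 2.46 TPM (adjusted p = 0.0295). In the uncalled fatty acid oxidation list (camera adjusted p = 0.773) the lipase inhibitor Angptl4 rose from 179 ± 7.0 to 391 ± 1.28 TPM (adjusted p = 0.00250). In the uncalled extracellular matrix list (camera adjusted p = 0.485) the protease inhibitor Timp1 rose from 1166 ± 118 to 3755 ± 896 TPM (adjusted p = 0.00743). Median and mean differed in sign for fatty acid oxidation (-0.06 and 0.08) and for the uncalled cell cycle list (0.03 and -0.04, camera adjusted p = 0.556).

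With all 5 groups fitted, the LPS count rested on all 4 libraries. It was 162 without LPS replicate 1, 374 without LPS replicate 2, 163 without saline replicate 1 and 112 without saline replicate 2. From the 4 libraries alone 226 passed, and 946 without the libraries labelled APRIL, 533 of them among the 539. Of 65 named genes past the threshold 31 kept it whichever library was left out. Saa3, Cxcl5, Il1b, Cfb, H2-K1, Gbp2, Ddit3 and G0s2 were among these, and Car3, Arg1, Mmp3, Dcn, Adrb3 and Cebpb were not. The ribosomal protein call ended without LPS replicate 1 (adjusted p = 0.0701), LPS replicate 2 (0.106), saline replicate 1 (0.0544) or saline replicate 2 (0.112) and with median-ratio scaling (0.0923). For insulin and glucose genes it ended without LPS replicate 1 (0.218), LPS replicate 2 (0.0632) or saline replicate 2 (0.156). For lipolysis genes it ended without LPS replicate 2 (0.192) or saline replicate 1 (0.0668). The respiratory chain call ended without LPS replicate 2 (0.128) or saline replicate 2 (0.160). The adipocyte identity call ended without LPS replicate 2 (0.0825) and the cAMP/CREB call without LPS replicate 1 (0.0816). The uncalled macrophage list went both ways: called lower without LPS replicate 1 (adjusted p = 0.0241), and higher without LPS replicate 2 (1.40e-04) or saline replicate 1 (0.0160). Endothelial markers were called lower without LPS replicate 1 (0.0480) or saline replicate 1 (0.0103). Also lower were fatty acid synthesis (0.0442) and T and NK lymphocyte markers (0.0480) without LPS replicate 1, and the cell cycle (0.0129) without LPS replicate 2.

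Norepinephrine against saline shows the response to the adrenergic transmitter that drives lipolysis and thermogenesis in fat. With norepinephrine, some genes of fatty acid oxidation, thermogenesis and lipid handling rose and some of the endoplasmic reticulum stress response fell. Pck1 (mm10 ENSMUSG00000027513, chromosome 2, 173153048 to 173159273) makes the glycerol backbone for fatty acid re-esterification. It showed the largest rise among genes with a mean of 5 TPM or more over the 10 libraries, from 3.91 ± 0.405 to 53.7 ± 3.41 TPM (log2 fold change 3.48 ± 0.41, adjusted p = 0.0258). Ucp1, the uncoupling protein of thermogenic adipocytes, rose from 0.0847 ± 0.0546 to 19.6 ± 9.46 TPM (log2 fold change 4.17 ± 0.54, adjusted p = 0.0280). Sdf2l1, a chaperone component of the endoplasmic reticulum, showed the largest fall among them, from 72.5 ± 9.14 to 16.6 ± 3.82 TPM (log2 fold change -2.07 ± 0.23, adjusted p = 0.0237). By limma, 87 genes rose and 12 fell at a false discovery rate of 0.05. With median-ratio scaling 107 rose and 38 fell. Over 13885 genes of known GC content and length, 85 rose and 11 fell before a correction for both, and 74 and 36 after it. At an unadjusted p under 0.05 there were 2489, where chance alone would give 708.3.

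The lists of fatty acid oxidation, thermogenic and lipid-handling genes were called higher with norepinephrine. Of 17 genes of fatty acid uptake and oxidation 4 rose and 0 fell (15 and 0 adjusted over the list alone). Such genes had a relative median of 1.00 (camera adjusted p = 1.51e-12, 0.312 with an estimated correlation). The mitochondrial carnitine carrier Slc25a20 rose from 25.01 ± 1.31 to 54.2 ± 7.35 TPM (adjusted p = 0.0258) and the acyl-CoA dehydrogenase Acadl from 125 ± 3.42 to 343 ± 15.2 TPM (adjusted p = 0.0258). Angptl4 rose from 179 ± 7.0 to 317 ± 40.4 TPM (adjusted p = 0.0337). Acaa1b, a peroxisomal thiolase outside the list, rose from 21.7 ± 8.52 to 243 ± 38.7 TPM (adjusted p = 0.0476). Of 17 thermogenic genes 2 rose and 0 fell (10 and 1 adjusted over the list alone). Set against all genes, they had a relative median of 1.23 (camera adjusted p = 6.96e-06, 0.312 with an estimated correlation). Beside Ucp1 the fatty acid elongase Elovl3 rose, from 0.134 ± 0.0498 to 4.47 ± 2.85 TPM (adjusted p = 0.0444). Cidea stood at 0.626 ± 0.0550 TPM with saline and 11.4 ± 5.25 with norepinephrine (adjusted p = 0.0577). Of 20 lipolysis and lipid droplet genes 2 rose and 0 fell (6 and 0 adjusted over the list alone). This list had a relative median of 0.67 (camera adjusted p = 7.79e-05, 0.490 with an estimated correlation). The droplet coat protein Plin5 rose from 2.58 ± 0.321 to 15.6 ± 1.24 TPM (adjusted p = 0.0476) and Plin2 from 387 ± 27.5 to 989 ± 13.5 TPM (adjusted p = 0.0258). Of 18 adipocyte identity genes 1 rose and 0 fell (3 and 0 adjusted over the list alone). Their relative median was 0.51 (camera adjusted p = 0.000456, 0.491 with an estimated correlation). The gene that rose was the retinol carrier Rbp4, from 152 ± 4.51 to 431 ± 104 TPM (adjusted p = 0.0476). Of 20 fatty acid and triglyceride synthesis genes 1 rose and 0 fell (3 and 1 adjusted over the list alone). The list's relative median was 0.44 (camera adjusted p = 0.00402, 0.619 with an estimated correlation). The phosphatidate phosphatase Lpin1 rose from 24.8 ± 0.925 to 64.5 ± 1.05 TPM (adjusted p = 0.0337). The nuclear-encoded respiratory chain was called higher, and of 23 genes 0 rose and 0 fell (2 and 0 adjusted over the list alone) by limma, with 10 higher and 0 lower at an unadjusted p under 0.05. As a list they had a relative median of 0.49 (camera adjusted p = 3.24e-07, 0.490 with an estimated correlation). Mitochondrially encoded genes were called lower, and of 13 genes 0 rose and 0 fell (the same adjusted over the list alone) by limma, with 0 higher and 4 lower at an unadjusted p under 0.05. Across the list the relative median was -0.38 (camera adjusted p = 0.00410, 0.491 with an estimated correlation). The cAMP/CREB list, named for the second messenger of adrenergic receptors, was called higher, and of 22 genes 2 rose and 0 fell (5 and 0 adjusted over the list alone). Relative to all genes their median stood at 0.14 (camera adjusted p = 0.0181, 0.490 with an estimated correlation). The risers were Pck1 and Sik1 (log2 fold change 0.98, adjusted p = 0.0476). Outside these lists, the fatty acid receptor Ffar4 rose from 3.28 ± 0.0945 to 16.5 ± 2.91 TPM (adjusted p = 0.0220) and the kinase Pim3 from 18.4 ± 0.709 to 72.6 ± 7.18 TPM (adjusted p = 0.0220). Depp1, Sema3g, Clstn3, Nos2 and Cd55 completed the 10 largest rises at log2 fold changes of 2.80, 2.63, 2.48, 2.37 and 2.28. Nos2 was the single riser of the acute-phase list (19 tested, camera adjusted p = 0.241).

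The lists of stress-response, cell cycle and cholesterol genes were called lower with norepinephrine. Of 20 genes of the unfolded protein and integrated stress response 0 rose and 3 fell (2 and 14 adjusted over the list alone). Together they had a relative median of -0.83 (camera adjusted p = 3.56e-10, 0.268 with an estimated correlation). Ddit3 fell from 123 ± 15.6 to 43.7 ± 0.557 TPM (adjusted p = 0.0204) and Trib3 from 38.5 ± 3.14 to 13.4 ± 0.630 TPM (adjusted p = 0.0280), and Derl3 outside the list fell from 27.9 ± 7.30 to 6.97 ± 0.602 TPM (adjusted p = 0.0204). Of 25 cell cycle genes 0 rose and 0 fell (the same adjusted over the list alone) by limma, with 0 higher and 20 lower at an unadjusted p under 0.05. Such genes had a relative median of -0.87 (camera adjusted p = 1.51e-12, 0.490 with an estimated correlation). The helicase subunit Mcm5 stood at 9.47 ± 1.27 TPM with saline and 3.86 ± 2.11 with norepinephrine (adjusted p = 0.139). Of 19 cholesterol synthesis genes 0 rose and 0 fell (1 and 6 adjusted over the list alone) by limma, with 1 higher and 8 lower at an unadjusted p under 0.05. Set against all genes, they had a relative median of -0.31 (camera adjusted p = 5.49e-06, 0.244 with an estimated correlation). The hypoxia list was called higher, and of 19 genes 0 rose and 0 fell (11 and 0 adjusted over the list alone) by limma, with 11 higher and 0 lower at an unadjusted p under 0.05. This list had a relative median of 0.58 (camera adjusted p = 3.24e-07, 0.312 with an estimated correlation). Hif1a, the oxygen-sensing factor outside the list, fell from 172 ± 8.78 to 103 ± 1.79 TPM (adjusted p = 0.0280). Insulin and glucose genes were called higher, and of 20 genes 1 rose and 0 fell (13 and 0 adjusted over the list alone). Their relative median was 0.54 (camera adjusted p = 4.18e-07, 0.490 with an estimated correlation). The riser was the insulin receptor substrate Irs2, from 5.28 ± 0.175 to 11.6 ± 0.290 TPM (adjusted p = 0.0476). MHC class I genes were called higher, and of 11 genes 0 rose and 0 fell (the same adjusted over the list alone) by limma, with 5 higher and 0 lower at an unadjusted p under 0.05. The list's relative median was 0.39 (camera adjusted p = 0.000456, 0.490 with an estimated correlation). Cytokines and chemokines were called lower, and of 21 genes 0 rose and 0 fell (0 and 2 adjusted over the list alone) by limma, with 1 higher and 5 lower at an unadjusted p under 0.05. As a list they had a relative median of -0.15 (camera adjusted p = 0.0145, 0.490 with an estimated correlation). Preadipocyte markers were called lower, and of 15 genes 0 rose and 0 fell (the same adjusted over the list alone) by limma, with 1 higher and 3 lower at an unadjusted p under 0.05. Across the list the relative median was -0.23 (camera adjusted p = 0.0181, 0.490 with an estimated correlation). Clu, Plk2, Mthfd2, Dio3 and Cyb5r1 completed the 10 largest falls at log2 fold changes of -1.24, -1.20, -1.03, -1.02 and -0.95. The metallothionein Mt1 rose from 977 ± 124 to 2173 ± 440.2 TPM (adjusted p = 0.0487) in an uncalled NRF2 list (camera adjusted p = 0.241). The uncalled p53 list was scored lower (camera adjusted p = 0.820) with a median of 0.03 and a mean of 0.04.

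With all 5 groups fitted, norepinephrine gene calls needed all 4 libraries. By limma 0 genes passed without norepinephrine replicate 1 (1415 at an unadjusted p under 0.05), 1 without norepinephrine replicate 2, 1 without saline replicate 1 and 1 without saline replicate 2. Of 32 named genes past the threshold 0 kept it whichever library was left out. The count was 55 unfiltered, 43 at a pseudocount of 0.1 and 61 without mitochondrially encoded genes. Without the libraries labelled APRIL it was 854, with all 99, but leaving out more was not tested. The call of mitochondrially encoded genes ended without saline replicate 2 (adjusted p = 0.0532) and that of cAMP/CREB targets without norepinephrine replicate 1 (0.0683). The preadipocyte call ended without norepinephrine replicate 2 (0.0511) and that of cytokines and chemokines with median-ratio scaling (0.0570). The uncalled interferon list went both ways, called higher without norepinephrine replicate 1 (adjusted p = 6.89e-09) and lower without norepinephrine replicate 2 (0.0124). Without norepinephrine replicate 1 or saline replicate 2, lists called lower were macrophage markers (3.58e-06 and 0.00181), the extracellular matrix (0.00141 and 0.00433) and NF-kB genes (0.0156 and 0.0471). Smooth muscle was called lower without norepinephrine replicate 2 (0.0122) or saline replicate 1 (0.0184). So were T and NK lymphocyte markers without norepinephrine replicate 1 (0.0471) and endothelial markers without saline replicate 1 (0.0263).

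**Figure D2:**
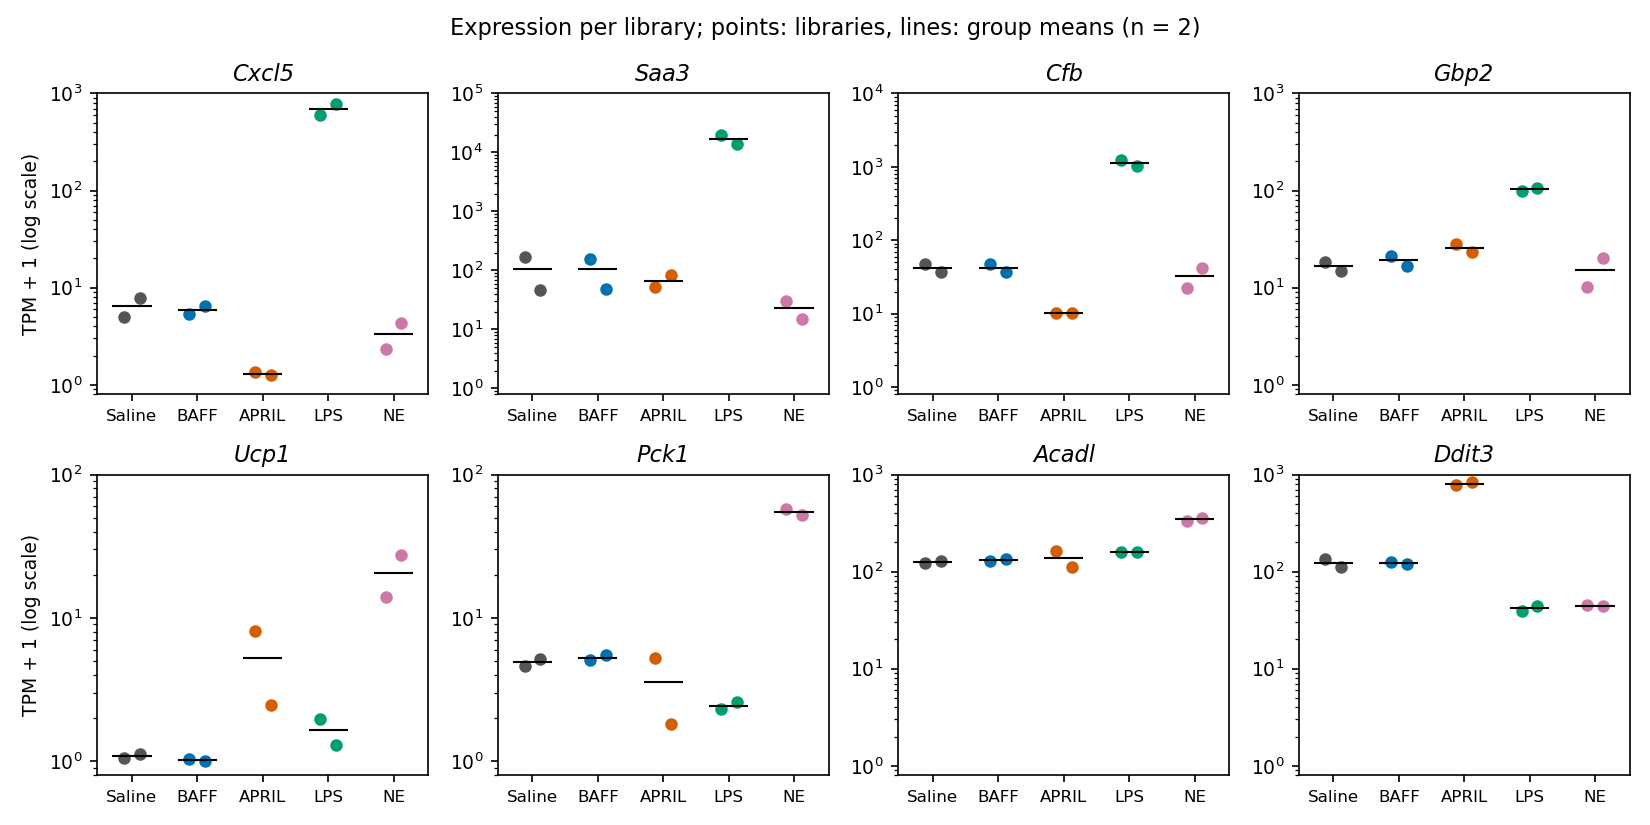
TPM + 1 on a log axis for 8 named genes in the 5 groups, points for libraries and lines for group means (n = 2), NE standing for norepinephrine. Cxcl5, Saa3, Cfb and Gbp2 are highest with LPS. Ucp1, Pck1 and Acadl are highest with norepinephrine, and Ddit3 in the libraries labelled APRIL.

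BAFF against saline asks which transcripts respond to the recombinant ligand over its vehicle. By limma 0 genes rose with BAFF and 2 fell. The 2 genes that fell hold identical values in all 10 libraries and were named after their values were seen. They are Gm7336 (mm10 ENSMUSG00000078636, chromosome 7, 51746647 to 51747878), a processed pseudogene of the glycolytic gene Gapdh, and ENSMUSG00000080830, which has no symbol. Both Gm7336 and ENSMUSG00000080830 stood at 12.8 ± 3.67 TPM with saline and 0.212 ± 0.300 with BAFF (log2 fold change -3.51 ± 0.23, adjusted p = 0.00359), lower in 2 of 2 BAFF libraries. With norepinephrine both rose, to 37.2 ± 5.35 TPM (log2 fold change 1.48, adjusted p = 0.0469). Gapdh itself stood at 91.8 ± 35.4 TPM with saline and 23.6 ± 9.40 with BAFF (log2 fold change -1.92, adjusted p = 0.996). At an unadjusted p under 0.05 there were 403 genes, where chance alone would give 708.3, and that count was 672 without the libraries labelled APRIL and 1056 from the 4 libraries alone.

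The genes of smallest p that did not pass began with the ribosomal protein gene Rps7, at 33.0 ± 5.87 TPM with saline and 15.9 ± 1.76 with BAFF (adjusted p = 0.518). Ccdc73, Frmd4a, Bcas3 and Dnm1 followed, each with an adjusted p of 0.996. No member of any of the 34 fixed lists passed by limma with BAFF, over all genes or adjusted over the list alone. By camera, mitochondrially encoded genes were called lower (13 tested, 0 higher and 0 lower at an unadjusted p under 0.05). Relative to all genes their median stood at -0.16 (camera adjusted p = 0.000533, 0.968 with an estimated correlation). The most abundant, mt-Atp8, stood at 125623 ± 8368 TPM with saline and 92612 ± 29448 with BAFF. The nuclear-encoded respiratory chain was also called lower (23 tested, 0 higher and 0 lower at an unadjusted p under 0.05). Together they had a relative median of -0.07 (camera adjusted p = 0.0376, 0.968 with an estimated correlation). The chain's own median of 0.04 and mean of 0.01 were above 0. Cox4i1 of that chain stood at 191 ± 18.2 TPM with saline and 143 ± 27.7 with BAFF. The other 27 lists were not called, with camera adjusted p from 0.0728 to 0.959. MHC class I genes had a relative median of 0.11 (camera adjusted p = 0.0728). Interferon-stimulated genes, with 0 higher and 0 lower at an unadjusted p under 0.05, had one of 0.21 (adjusted p = 0.447). NF-kB genes, which TNF-family receptors engage, had a relative median of 0.02 (adjusted p = 0.938). Of these, the feedback regulator Bcl3 stood at 76.9 ± 0.0119 and 90.2 ± 4.05 TPM with saline and BAFF, and Nfkbiz at 7.46 ± 0.654 and 8.70 ± 0.573 TPM. Relative medians were -0.05 for adipocyte identity (adjusted p = 0.175), -0.04 for lipolysis (0.0754) and -0.09 for thermogenic genes (0.125). They were -0.06 for cytokines and chemokines (adjusted p = 0.142), -0.09 for macrophage markers (0.0728), -0.10 for skeletal muscle (0.130) and -0.11 for T and NK lymphocytes (0.269). Several lists, adipocyte identity and thermogenic genes among them, were scored lower by camera with medians and means above 0, since camera sets a list against all other genes. Fatty acid synthesis, cell cycle and Schwann markers were scored lower with relative medians of 0.01, 0.03 and 0.02. Cholesterol synthesis and endothelial markers were scored higher with -0.04 and -0.01.

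By limma the gene calls with BAFF ended with a pseudocount of 0.1 (0 genes, 409 at an unadjusted p under 0.05) and with the 4 libraries alone (0 genes, 1056 at an unadjusted p under 0.05). There was 1 gene when identical values were counted once, 4 genes without saline replicate 2 (1 rise and 3 falls), 3 with a mean of at least 5 TPM (1 rise and 2 falls) and 12 without a filter on low values (5 rises and 7 falls). The mitochondrial call ended without BAFF replicate 1 (direction higher, adjusted p = 0.979) and without saline replicate 2 (0.340). The respiratory chain call ended without BAFF replicate 1 (0.669), saline replicate 2 (0.490) or the libraries labelled APRIL (0.105). The macrophage list was called lower without the libraries labelled APRIL (adjusted p = 0.0441), BAFF replicate 1 (0.00409) or saline replicate 2 (1.12e-06). Interferon-stimulated genes were called higher with median-ratio scaling (adjusted p = 0.0176). Ribosomal proteins were called lower without BAFF replicate 1 (0.00409) and higher without BAFF replicate 2 (0.00299). Without BAFF replicate 2 there were 9 list calls, and without saline replicate 1 there were 6. In both cases MHC class I (0.00592 and 9.59e-04) and the extracellular matrix (0.00784 and 0.0384) were called higher and skeletal muscle lower (6.83e-04 and 3.94e-05). Without BAFF replicate 2 lipolysis (0.00194), adipocyte identity (0.00797) and fatty acid synthesis (0.0128) were called lower, and without saline replicate 1 hypoxia genes higher (0.0232). In simulated changes added to these values for 200 genes a draw, 7.99% of 1.5-fold, 44.0% of 2-fold and 78.7% of 4-fold changes were called.

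The libraries labelled APRIL were set against saline to ask the same of the other ligand. The difference in Y-linked transcripts, at most 0.775 against at least 93.8 TPM, runs along with every gene of this comparison. By limma, 4694 genes were higher and 3542 lower in these libraries, 58.1% of those tested, and 2275 and 1643 differed at least 2-fold. With median-ratio scaling 4184 were higher and 4271 lower, so the excess of rises did not hold under that scaling. The inducible heat-shock chaperone Hspa1b showed the largest rise among the named genes, from 12.9 ± 2.49 to 2339 ± 1959.7 TPM (log2 fold change 7.09 ± 0.52, adjusted p = 3.26e-05). The stress cytokine Gdf15 rose from 4.04 ± 0.509 to 485 ± 243 TPM (log2 fold change 6.50 ± 0.54, adjusted p = 5.70e-05). Slc16a6 (mm10 ENSMUSG00000041920, chromosome 11, 109450855 to 109473598), of the monocarboxylate transporter family, rose from 2.10 ± 0.118 to 119.6 ± 14.2 TPM (log2 fold change 5.28 ± 0.17, adjusted p = 2.60e-06). The Y-linked translation factor gene Eif2s3y showed the largest fall, from 54.6 ± 3.15 to 0.251 ± 0.247 TPM (log2 fold change -5.49 ± 0.15, adjusted p = 2.16e-06). Next came Wfdc21, from 175 ± 8.87 to 3.29 ± 1.85 TPM (adjusted p = 1.26e-05), and the gelatinase Mmp9, from 147 ± 17.8 to 3.56 ± 2.59 TPM (adjusted p = 0.000409). Immediate-early and clock-related genes were among the other largest rises. These include Jun (log2 fold change 5.04, adjusted p = 2.79e-06), Zfp36 (log2 fold change 4.54, adjusted p = 6.35e-06), Nr4a3 (log2 fold change 4.53, adjusted p = 9.25e-05), Nr1d1 (log2 fold change 4.97, adjusted p = 6.58e-06) and Ciart (log2 fold change 5.13, adjusted p = 1.75e-05). Cxcl1 (log2 fold change 4.97, adjusted p = 2.67e-05) and Hspa1a (log2 fold change 6.28, adjusted p = 6.54e-05) completed the 10. The other largest falls were those of Ddx3y, Gapdh, G0s2, Tuba1a, Lrrc17, Apln and Sfrp2, with log2 fold changes from -4.84 to -4.14. For Gapdh (-4.68) reads can be shared with copies, and TPM summed over 69 Gapdh-like IDs was 63.3 ± 3.21 in these libraries and 181 ± 31.2 with saline, 0.349 of it. Autosomes held 96.3% of the 8107 calls with a known position.

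The lists of cAMP/CREB targets, p53 targets and NF-kB genes were called higher in the libraries labelled APRIL, which stand apart by their Y-linked sum of at most 0.775 TPM. Of 22 cAMP/CREB targets 18 rose and 1 fell (18 and 2 adjusted over the list alone). Such genes had a relative median of 2.07 (camera adjusted p = 0.000124, 0.480 with an estimated correlation). Risers included Sik1 (log2 fold change 3.81, adjusted p = 5.02e-06), the AP-1 subunit Junb (log2 fold change 4.07, adjusted p = 8.77e-06) and the phosphatase Dusp1 (log2 fold change 4.08, adjusted p = 9.86e-06). Of 15 p53 targets 11 rose and 1 fell (12 and 1 adjusted over the list alone). Set against all genes, they had a relative median of 1.68 (camera adjusted p = 0.000149, 0.480 with an estimated correlation). Mdm2, the ligase that degrades p53, rose from 40.8 ± 1.502 to 629.8 ± 74.1 TPM (adjusted p = 2.16e-06) and the death effector Bbc3 from 14.7 ± 0.698 to 128 ± 10.1 TPM (adjusted p = 8.60e-06). Of 21 NF-kB genes 15 rose and 1 fell (the same adjusted over the list alone). This list had a relative median of 1.55 (camera adjusted p = 0.000266, 0.730 with an estimated correlation). Bcl3 (log2 fold change 1.71, adjusted p = 1.21e-05), Relb (log2 fold change 2.07, adjusted p = 1.85e-05) and Traf2 (log2 fold change 2.29, adjusted p = 2.03e-05) rose. The stress response was not called by camera (20 tested, 6 rose and 3 fell, the same adjusted over the list alone, adjusted p = 0.419), although Ddit3 rose from 123 ± 15.6 to 805 ± 45.3 TPM (adjusted p = 6.26e-06). Nor was the NRF2 list (16 tested, 9 rose and 2 fell, the same adjusted over the list alone, adjusted p = 0.121). There the autophagy receptor Sqstm1 (log2 fold change 2.73, adjusted p = 2.43e-05) and the glutathione synthesis gene Gclc (log2 fold change 2.67, adjusted p = 5.40e-05) rose. Thermogenic genes were not called (17 tested, 10 rose and 2 fell, the same adjusted over the list alone, adjusted p = 0.0693). The coactivator Ppargc1a (log2 fold change 3.297, adjusted p = 1.56e-05) and Cidea (log2 fold change 3.29, adjusted p = 0.001004) rose. Cytokines and chemokines were not called (21 tested, 8 rose and 3 fell, the same adjusted over the list alone, adjusted p = 0.264), though Il6 rose (log2 fold change 3.97, adjusted p = 7.49e-05). MHC class I (11 tested, 4 rose and 1 fell, the same adjusted over the list alone, adjusted p = 0.436) and mitochondrially encoded genes (13 tested, 4 rose and 2 fell, the same adjusted over the list alone, adjusted p = 0.615) were not called either.

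Proliferation, matrix and lipid synthesis lists were called lower in the libraries labelled APRIL, again along with the Y-linked difference (0.775 TPM or less against 93.8 or more). Of 25 cell cycle genes 3 rose and 20 fell (the same adjusted over the list alone). Their relative median was -2.19 (camera adjusted p = 0.000144, 0.779 with an estimated correlation). The mitotic kinase Aurkb (log2 fold change -2.07, adjusted p = 8.74e-05) and the cyclin Ccna2 (log2 fold change -3.94, adjusted p = 0.000211) fell. Of 21 extracellular matrix genes 0 rose and 14 fell (the same adjusted over the list alone). The list's relative median was -1.08 (camera adjusted p = 0.000149, 0.730 with an estimated correlation). The fibrillar collagen genes Col5a1 (log2 fold change -2.27, adjusted p = 1.72e-05) and Col3a1 (log2 fold change -2.95, adjusted p = 3.46e-05) fell. Of 11 smooth muscle and pericyte markers 0 rose and 10 fell (the same adjusted over the list alone), the smooth muscle actin Acta2 among the falls (log2 fold change -2.57, adjusted p = 0.000112). As a list they had a relative median of -1.66 (camera adjusted p = 0.000438, 0.480 with an estimated correlation). Of 20 fatty acid and triglyceride synthesis genes 1 rose and 12 fell (2 and 12 adjusted over the list alone). Across the list the relative median was -1.13 (camera adjusted p = 0.00433, 0.818 with an estimated correlation). The elongase Elovl6 (log2 fold change -1.84, adjusted p = 5.73e-05) and the fatty acid synthase Fasn (log2 fold change -2.80, adjusted p = 0.000497) fell. Of 19 cholesterol synthesis genes 2 rose and 12 fell (the same adjusted over the list alone). Relative to all genes their median stood at -0.77 (camera adjusted p = 0.00433, 0.480 with an estimated correlation). Idi1 (log2 fold change -2.18, adjusted p = 1.42e-05) fell. Of 19 acute-phase genes 2 rose and 12 fell (the same adjusted over the list alone). Together they had a relative median of -1.23 (camera adjusted p = 0.00628, 0.480 with an estimated correlation). The haptoglobin gene Hp (log2 fold change -2.82, adjusted p = 0.000268) and Cfb (log2 fold change -2.02, adjusted p = 0.000605) fell. Of 19 hypoxia genes 5 rose and 13 fell (the same adjusted over the list alone). Such genes had a relative median of -1.42 (camera adjusted p = 0.0146, 0.739 with an estimated correlation). Of 20 insulin and glucose genes 3 rose and 12 fell (the same adjusted over the list alone), and Ldha, in both lists, fell (log2 fold change -1.35, adjusted p = 3.28e-05). Set against all genes, they had a relative median of -0.88 (camera adjusted p = 0.0131, 0.779 with an estimated correlation). Preadipocyte markers (15 tested, 2 rose and 9 fell, the same adjusted over the list alone, camera adjusted p = 0.0123, 0.675 with an estimated correlation) were called lower too. So were endothelial markers (12 tested, 0 rose and 6 fell, or 0 and 7 adjusted over the list alone, camera adjusted p = 0.0143, 0.730 with an estimated correlation) and ribosomal proteins (26 tested, 0 rose and 10 fell, or 0 and 7 adjusted over the list alone, camera adjusted p = 0.00935, 0.818 with an estimated correlation).

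Other lists were mixed or small in the libraries labelled APRIL, with the Y-linked difference (at most 0.775 TPM) running along with them. Adipocyte identity genes were not called (18 tested, 2 rose and 9 fell, the same adjusted over the list alone, camera adjusted p = 0.0693), with Pparg (log2 fold change 1.47, adjusted p = 0.00101) and Adipoq (log2 fold change -2.51, adjusted p = 0.00180). Lipolysis genes were not called (20 tested, 4 rose and 6 fell, the same adjusted over the list alone, camera adjusted p = 0.286), and Adrb3 fell from 130.0 ± 15.1 to 9.04 ± 4.79 TPM (adjusted p = 3.77e-05). The macrophage list (19 tested, 0 rose and 1 fell, the same adjusted over the list alone, camera adjusted p = 0.0954) was not called. Neither were the respiratory chain (23 tested, 0 rose and 4 fell, or 0 and 2 adjusted over the list alone, camera adjusted p = 0.103) and the Schwann and neural list (5 tested, 1 rose and 2 fell, the same adjusted over the list alone, camera adjusted p = 0.419). Fatty acid oxidation genes (17 tested, 4 rose and 2 fell, or 4 and 1 adjusted over the list alone, camera adjusted p = 0.533) had a median of -0.18 and a mean of 0.10. Scored lower by camera with medians of 0.16, 0.61 and 0.17 were 3 uncalled lists. They are skeletal muscle (8 tested, 0 rose and 0 fell, the same adjusted over the list alone, camera adjusted p = 0.844), T and NK lymphocytes (5 tested, 1 rose and 1 fell, or 2 and 2 adjusted over the list alone, camera adjusted p = 0.849) and interferon-stimulated genes (27 tested, 3 rose and 1 fell, or 1 and 0 adjusted over the list alone, camera adjusted p = 0.934). In lists too small to test, Ighm, the single B-lymphocyte gene tested, rose from 1.97 ± 0.170 to 5.41 ± 0.452 TPM (adjusted p = 0.00725). The keratin Krt19 fell from 9.49 ± 0.0951 to 3.26 ± 0.738 TPM (adjusted p = 0.00457) as 1 of 2 falls among 3 mesothelial and epithelial genes. Cxcr2, 1 of 3 neutrophil and mast cell genes, rose from 0.637 ± 0.0897 to 1.70 ± 0.750 TPM (adjusted p = 0.0403).

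Of 92 named genes past the threshold for the libraries labelled APRIL 90 kept it whichever library was left out. The exceptions were Cxcr2 and Tlr4, which rose from 11.1 ± 0.827 to 17.0 ± 4.87 TPM (adjusted p = 0.0382). For Cxcr2 the adjusted p was 0.190 without APRIL replicate 2, 0.149 without saline replicate 1 and 0.0989 without saline replicate 2. For Tlr4 it was 0.172 without APRIL replicate 1, 0.157 without saline replicate 1 and 0.0817 without saline replicate 2. Without APRIL replicate 1 the calls ended for ribosomal proteins (adjusted p = 0.0611), endothelial markers (0.0815) and preadipocyte markers (0.0815). Without APRIL replicate 2 the call ended for insulin and glucose genes (adjusted p = 0.0814). Lists uncalled with all libraries were added too. Without APRIL replicate 1 the respiratory chain (adjusted p = 1.92e-05), adipocyte identity (0.00133), lipolysis (0.0373) and fatty acid oxidation (0.0373) were called lower. Without APRIL replicate 2 thermogenic and NRF2 genes were called higher (0.00558 each), and without saline replicate 2 macrophage markers lower (0.0119). With median-ratio scaling thermogenic genes were called higher (0.0374) and the respiratory chain lower (0.0429).

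BAFF against the libraries labelled APRIL cannot compare the ligands alone. For that label a Y-linked sum of at most 0.775 TPM argues against male mice. By limma, 4003 genes were higher and 4112 lower with BAFF. From the libraries labelled APRIL to those with BAFF the largest rise was that of Eif2s3y, from 0.251 ± 0.247 to 54.2 ± 2.48 TPM (log2 fold change 5.48 ± 0.15, adjusted p = 2.81e-06). Wfdc21 (log2 fold change 5.35, adjusted p = 1.45e-05), Mmp9 (log2 fold change 5.15, adjusted p = 0.000432), Ddx3y (log2 fold change 4.88, adjusted p = 2.81e-06) and G0s2 (log2 fold change 4.70, adjusted p = 3.52e-06) followed. The largest fall was that of Hspa1b, from 2339 ± 1959.7 to 15.4 ± 0.924 TPM (log2 fold change -6.85 ± 0.52, adjusted p = 4.08e-05). Gdf15 (log2 fold change -6.46, adjusted p = 6.20e-05), Hspa1a (log2 fold change -6.23, adjusted p = 7.25e-05), Slc16a6 (log2 fold change -5.44, adjusted p = 3.12e-06) and Cxcl1 (log2 fold change -5.05, adjusted p = 2.80e-05) came next. By camera 15 lists were called, 11 higher and 4 lower with BAFF, and 0 with an estimated correlation (2 at an unadjusted p under 0.05). Lower were cAMP/CREB targets (relative median -2.12, camera adjusted p = 2.49e-05, 0.480 with an estimated correlation) and p53 targets (-1.62, camera adjusted p = 0.000100, 0.391 with an estimated correlation). So were NF-kB genes (-1.56, camera adjusted p = 0.000130, 0.690 with an estimated correlation) and thermogenic genes (-0.67, camera adjusted p = 0.0304, 0.744 with an estimated correlation). Higher were the cell cycle (relative median 2.39, camera adjusted p = 0.000172, 0.763 with an estimated correlation) and smooth muscle (1.60, camera adjusted p = 0.00106, 0.480 with an estimated correlation). The extracellular matrix (1.11, camera adjusted p = 0.000167, 0.690 with an estimated correlation) and 8 further lists were higher too, all 8 called lower for the libraries labelled APRIL against saline. Median and mean differed in sign for 2 uncalled lists, T and NK lymphocyte markers (-0.73 and 0.01) and fatty acid oxidation (0.24 and -0.05). Without APRIL replicate 1 the calls ended for ribosomal proteins (adjusted p = 0.0530), endothelial (0.0602) and preadipocyte markers (0.0840). Without APRIL replicate 2 it ended for insulin and glucose genes (adjusted p = 0.0999). Added calls were the respiratory chain (8.77e-05) and adipocyte identity (0.00255), higher without APRIL replicate 1, and NRF2 genes, lower without APRIL replicate 2 (0.00241).

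**Figure D3:**
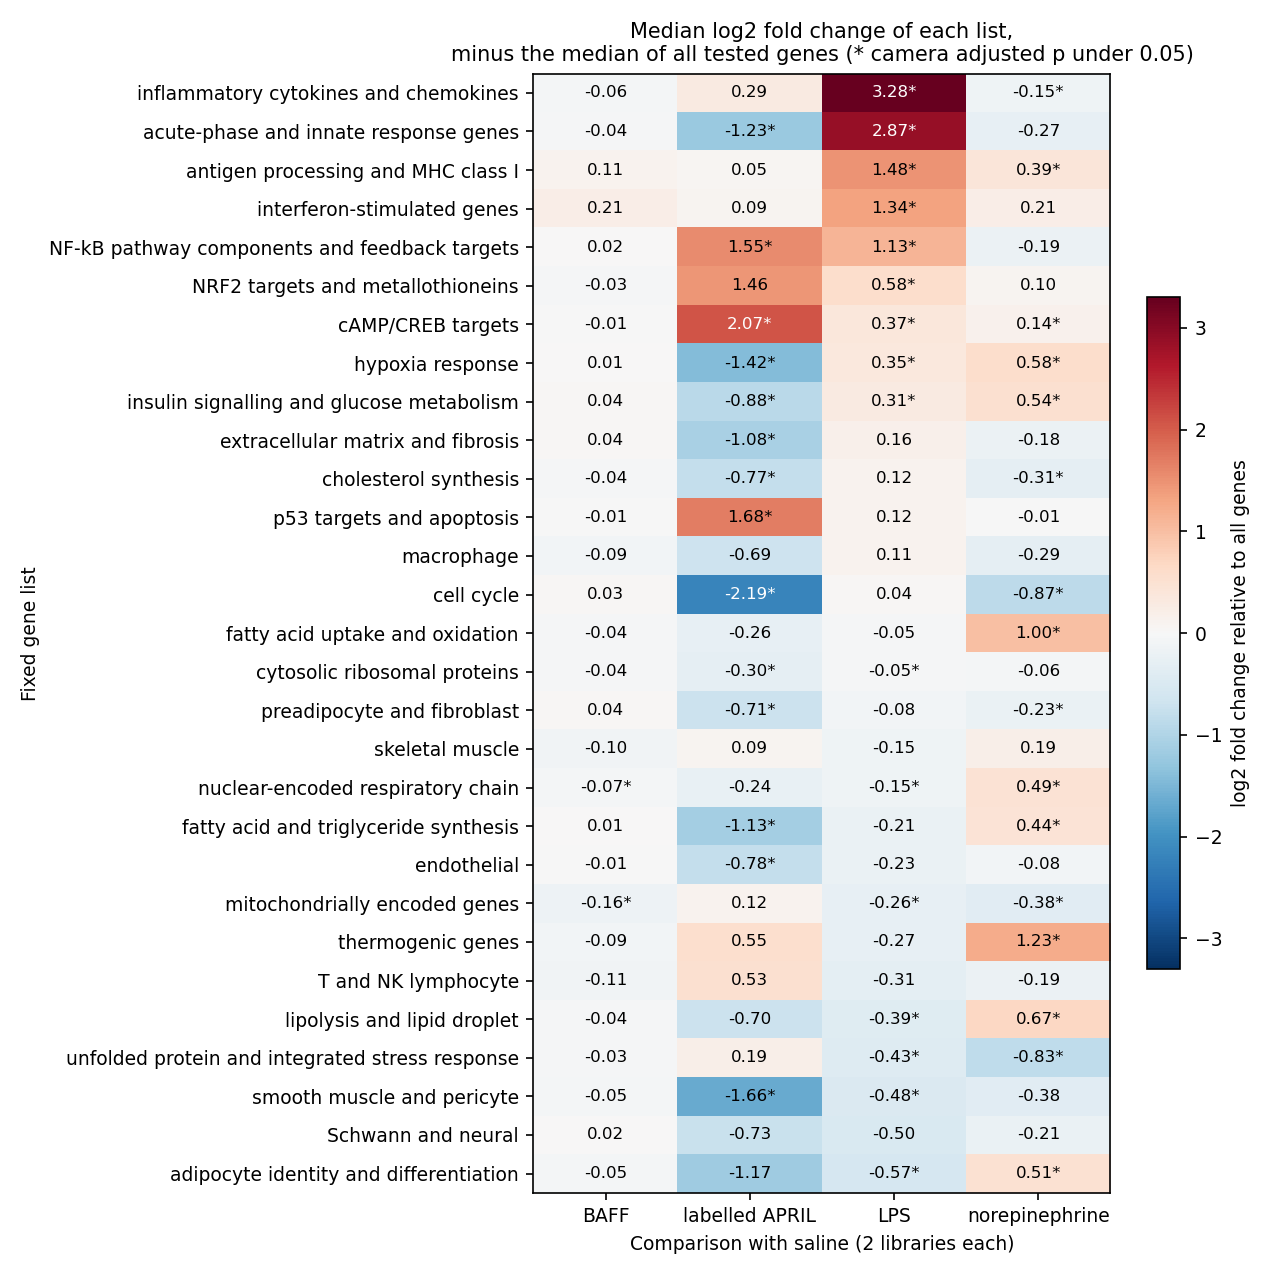
Heat map of the median log2 fold change of each of 29 fixed lists minus that of all tested genes, in the 4 comparisons with saline (2 libraries a group), with an asterisk for a camera adjusted p under 0.05. The inflammatory lists stand out with LPS at 3.28 and 2.87, and with norepinephrine thermogenic genes at 1.23 and fatty acid oxidation at 1.00. The values with BAFF lie between -0.16 and 0.21.

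The comparisons share the saline libraries, which alone makes fold changes covary. LPS and norepinephrine had 16 rises in common where independent lists would share 2.5, and 6 falls where they would share 0.11. Ddit3, Trib3 and Derl3 fell with both, and 2 genes changed in opposite directions. The libraries labelled APRIL shared 150 rises and 94 falls with LPS, against 134.9 and 33.0 for independent lists, and 114 genes changed in opposite directions. With norepinephrine they shared 35 rises and 6 falls, against 28.8 and 3.0, and 29 genes changed in opposite directions. With BAFF they shared 2 falls against 0.50, the same 2 genes that moved in opposite directions with BAFF and norepinephrine. Across genes, which are not independent replicates, the covariance of log2 fold changes was 0.0483 for LPS and norepinephrine. It was 0.0798 for the libraries labelled APRIL and LPS and 0.0809 for those libraries and norepinephrine. Unchanged groups simulated against the same saline libraries gave means of 0.0338 to 0.0343, in draws that take the groups as independent of each other and give each gene 1 spread in all groups. With 1 saline library for each side the 3 covariances became 0.0258 or 0.00505, 0.0327 or 0.0612, and 0.0441 or 0.0518 for the 2 assignments. For BAFF the covariance was 0.0302 with the libraries labelled APRIL, 0.0271 with LPS and 0.0222 with norepinephrine. With 1 saline library for each side these became -0.00109 and -0.00427, -0.0184 and 0.00692, and -0.0130 and -0.00844. Leaving out saline replicate 1 or saline replicate 2 raised each of the 6 covariances. LPS and norepinephrine then had 0.0925 and 0.0699, the libraries labelled APRIL with LPS 0.120 and 0.105, and these with norepinephrine 0.111 and 0.117. For BAFF the values were 0.0578 and 0.0683 with the libraries labelled APRIL, 0.0690 and 0.0510 with LPS, and 0.0537 and 0.0564 with norepinephrine. Near-identical copies elsewhere in the genome, at 95% identity or more over at least 50.0% of the longest or the longest coding transcript, were found for 18 of 190 named genes searched, and TPM can shift between copies. They are Acaa1b, Cfb, Ciart, Cpt1b, Gapdh, Hspa1a, Hspa1b, Ldha, Oas1a, Rpl27, Rpl3, Rps7, Saa1, Tuba1a, mt-Co1, mt-Nd3, mt-Nd4 and mt-Nd4l.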

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

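Median-ratio scaling, mitochondrially encoded genes left out, identical values counted once, the libraries labelled APRIL left out and the crossed block were chosen after the results were seen, the other settings before. The files hold no counts, so 3 settings that need them (another count test, size factors, log2 CPM) were not run. A library left alone in its group is assumed to vary like the other groups. In the libraries labelled APRIL the count against saline kept within 1.5 times of 8236, from 6389 with a mean of at least 5 TPM to 8724 without a filter, and with the median-ratio scaling 4184 were higher and 4271 lower, so the excess of rises did not hold under that scaling. Against BAFF the range was 6223 to 8603. Of 249 named gene results, compared over all settings, 3063 values kept direction and side of the threshold, 85 moved past it, 373 fell short of it and 0 reversed. Unknown read depth limits what can be said of genes with low TPM.

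Counts of genes that moved by more than 1.5 times were these, and the cause was not tested except where stated. With BAFF (2 genes) the count was 12 without a filter on low values, 0 from the 4 compared libraries alone (1056 at an unadjusted p under 0.05), 0 with a pseudocount of 0.1 (409 at an unadjusted p under 0.05) and 1 with identical values counted once, which by construction removes 1 of the 2 genes. The 403 genes at an unadjusted p under 0.05 became 672 with the libraries labelled APRIL left out and 1027 with these left out and a block. With LPS (539) it was 226 from the 4 libraries alone, where fewer libraries carry the spread, 946 with the libraries labelled APRIL left out and 1705 with these left out and a replicate block. With norepinephrine (99) it was 55 without a filter, 43 with a pseudocount of 0.1, 61 with mitochondrially encoded genes left out, 167 with a replicate block, 854 with the libraries labelled APRIL left out and 1740 with these left out and a block. Leaving out each library in turn gave 2 to 4 genes with BAFF (4 without saline replicate 2), 112 to 374 with LPS (162 without LPS replicate 1, 163 without saline replicate 1, 112 without saline replicate 2) and 0 to 1 with norepinephrine (0 without norepinephrine replicate 1, 1415 at an unadjusted p under 0.05). Replicate numbers are in the labels without a stated meaning. Deviations from the group means correlated between same-numbered libraries at 0.272 to 0.479 over the 6 pairs of groups without the libraries labelled APRIL and at -0.108 to 0.026 over the 4 pairs with them. A block gave 2 genes with BAFF, 683 with LPS, 8531 in the libraries labelled APRIL and 8383 for BAFF against them, the last 8594 with their numbers crossed. Of list calls with LPS it ended those of lipolysis genes (adjusted p = 0.0502) and ribosomal proteins (0.0514). It added the smooth muscle list, lower with norepinephrine (0.0266), and the macrophage list, lower in the libraries labelled APRIL (0.0150) and higher with BAFF against them (0.0289).

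For lists, an estimated correlation in camera left 0 of 2 calls with BAFF, 0 of 14 in the libraries labelled APRIL, 2 of 16 with LPS, 0 of 16 with norepinephrine and 0 of 15 for BAFF against the libraries labelled APRIL, and the cause was not tested. At an unadjusted p under 0.05 it had 0, 2, 4, 4 and 2 lists in that order. The fry test, which asks about a list without setting it against other genes, called 0 with BAFF (0 at an unadjusted p under 0.05), 5 with LPS and 5 with norepinephrine, but 19 in the libraries labelled APRIL and 19 for BAFF against them, and the cause was not tested. The libraries labelled APRIL left out added the macrophage list with BAFF (adjusted p = 0.0441), fatty acid synthesis with LPS (0.00421) and smooth muscle with norepinephrine (0.0481), all lower. Leaving out each library gave 1 to 9 lists with BAFF (9 without BAFF replicate 2, 6 without saline replicate 1, 1 without saline replicate 2), 14 to 15 in the libraries labelled APRIL, 13 to 17 with LPS and 17 to 20 with norepinephrine, and the cause was not tested.

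Covariances of fold changes moved when each side had its own saline library, which by construction removes the shared control. They became -0.00109 and -0.00427 for BAFF with the libraries labelled APRIL (from 0.0302), -0.0184 and 0.00692 for BAFF with LPS (from 0.0271), -0.0130 and -0.00844 for BAFF with norepinephrine (from 0.0222), 0.0327 for the libraries labelled APRIL with LPS (from 0.0798), 0.0441 and 0.0518 for these with norepinephrine (from 0.0809) and 0.0258 and 0.00505 for LPS with norepinephrine (from 0.0483). Without a filter they were 0.0508 and 0.0519 for the libraries labelled APRIL with LPS and with norepinephrine, where more genes of low TPM enter. Leaving out each library gave, in the order of the pairs above, 0.0260 to 0.0683, 0.0157 to 0.0690, 0.0197 to 0.0564, 0.0649 to 0.120, 0.0660 to 0.117 and 0.0350 to 0.0925, the highest of each without saline replicate 1 or saline replicate 2.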

Other observations

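The correction for GC content and length, the muscle genes on no list and the correlation without muscle genes were set down before their results were seen, and all other tests of this section after. Heat-shock, clock and peroxisome genes were looked at in lists added after the values were seen. Of 16 cytosolic heat-shock chaperone genes 15 rose and 0 fell (the same adjusted over the list alone), with a relative median of 2.20, in the libraries labelled APRIL, whose Y-linked sum of at most 0.775 TPM sets them apart, among them Hspb1 (log2 fold change 2.62, adjusted p = 2.66e-05). Of 18 circadian clock genes 15 rose and 1 fell (the same adjusted over the list alone) in the same libraries, with a relative median of 1.998, among them Nr1d2 (log2 fold change 3.01, adjusted p = 2.60e-06). With norepinephrine 4 rose and 0 fell (7 and 2 adjusted over the list alone) of 18 clock genes, with Per3 (log2 fold change 0.77, adjusted p = 0.0399) and Dbp (log2 fold change 1.46, adjusted p = 0.0476), and of 15 peroxisome genes 2 rose and 0 fell (10 and 1 adjusted over the list alone), with the import factors Pex5 (log2 fold change 0.67, adjusted p = 0.0382) and Pex6 (log2 fold change 0.82, adjusted p = 0.0404). With LPS Per3 fell (log2 fold change -0.53, adjusted p = 0.0478), and of the 3 lists no other gene passed with LPS or BAFF.

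The 2 libraries labelled APRIL stand apart from the other 8. A bias of GC content or transcript length as the whole cause is argued against: after a correction for both in each library, 8135 of 13885 genes with known content and length passed against saline, beside 8125 before it, with 7368 in common. Male mice as source are argued against: in these libraries the 4 Y-linked genes summed to at most 0.775 TPM, elsewhere to at least 93.8. Other mice, without a Y chromosome, are a candidate explanation, of untested extent. The response to APRIL itself stays open and cannot be told apart from such a difference, because 0 libraries labelled APRIL had a Y-linked sum above 50.0% of the lowest of the other 8.

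The only 2 genes called with BAFF, Gm7336 and ENSMUSG00000080830, held equal values in 10 of 10 libraries, so identical values entered under 2 gene IDs may make a single transcript model count as 2 genes. Reads divided among near-identical Gapdh copies could lie behind their fall. Over 69 listed Gapdh-like IDs, both included, summed TPM with BAFF was 0.502 of saline (90.9 ± 3.13 against 181 ± 31.2). With identical values counted once the ratio was 0.539 (90.7 ± 2.83 against 168 ± 34.9), and 0.503 without the matching gene Peli2. With both identical IDs but without Peli2 it was 0.466. This argues against moves among the listed IDs alone, which would keep the sum. Moves to other copies stay open: of 164 reference genes matching Gapdh 68 are listed (ENSMUSG00000080830 makes 69) and 96 are not. No biological explanation was tested.

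Skeletal muscle transcripts were higher in replicate 2 than in replicate 1 of saline, BAFF, LPS and norepinephrine. The muscle list summed to 22.1 and 165 TPM in the 2 saline libraries, 32.6 and 125 with BAFF, 18.8 and 139 with LPS and 29.4 and 217 with norepinephrine, but to 153 and 33.0 in the libraries labelled APRIL, and its most abundant genes with saline were Mylpf (5.94 and 79.4 TPM) and Acta1 (6.57 and 22.2 TPM). More muscle cells in the replicate 2 cultures are a candidate source: of 28 tested muscle genes on no list 26 were higher in replicate 2 in all 4 groups, beside 15.8% of all 14166 genes, and 25 of the 28 were lower in replicate 2 of the libraries labelled APRIL, but whether same-numbered cultures share a preparation was not tested. Whether muscle genes alone tie same-numbered libraries together stays open: without the 8 tested genes of the list, the 6 correlations of deviations ran from 0.26 to 0.470, beside 0.272 to 0.479 with them, but leaving out 8 of 14166 genes can hardly move such a correlation. No biological explanation was tested, because the design gives none for replicate numbers.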
